A study of Mus musculus with 2 samples.

How the data were processed

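PolyA RNA from mouse heart was sequenced in 2 libraries, labelled GFP and COX8-AGO2, with 1 library per group. Per the labels' protocols, RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads and fragmented, and libraries were made with a NEBNext Ultra kit and amplified by PCR. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2 and StringTie 1.3.1, without saying which step each served. The counting tool, the use of strand, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

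The authors deposited 1 table with a row per gene, an Ensembl gene identifier, a symbol and, for each library, an estimated count and a TPM (transcript abundance scaled by length and library) value, per the file headers. The estimated counts were not normalized, and 7.23% of genes had a fractional value in at least 1 library. The deposited TPM values summed to nearly the same total in each library and divide reads by an effective gene length. The header of the GFP columns adds the prefix cTNT, which the labels do not explain. The table held 22063 gene rows, of which 30 had no symbol. For mtDNA it held the 13 mRNAs, so ribosomal and transfer RNAs of mtDNA do not enter any share. Dicer1 was not analysed here.

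Estimated counts were rounded to whole numbers. They summed to 14615982 (GFP) and 15065345 (COX8-AGO2). Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, so that a floor of 3 reads in a library equalled 0.201 (GFP) and 0.203 (COX8-AGO2) scaled CPM, and log2 ratios of COX8-AGO2 over GFP were taken after adding a prior of 0.5 reads to each library. Genes with a mean of at least 1 CPM were called measured. Exact Clopper-Pearson 95% intervals of the ratio, conditional on the sum of both counts, were computed with scipy 1.17.1 under Python 3.11.15; shares of reads have exact Clopper-Pearson intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Folds against a library with 0 reads were computed against the floor of 3 reads and written as at least that value.

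With 1 library per group no test between groups was possible and no gene was called by a test. Gene lists were described by the median log2 ratio of measured members, the number at least 1.5-fold apart, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 50 bins; this describes the 2 libraries only, and the match is loose in the most abundant bin, which holds the mtDNA mRNAs. The 30 gene lists, the 16 cell type marker lists and the naming rule were fixed before the data were examined. The rule named Ago2 and the 13 mtDNA-encoded mRNAs, the 12 genes with the highest and the 12 with the lowest ratio at a mean of at least 5 CPM (leaving out unnamed gene models, pseudogenes and immune receptor segments), and up to 4 members of each list with the largest absolute log2 ratio. Lists with fewer than 5 measured members have no percentile. Another 7 lists, and the pathway annotation in the deposited table (pathways of 10 to 300 measured genes, 2000 random lists each), were examined afterwards and appear only among the closing observations, except the Cell cycle pathway, which is set beside the fixed list. Symbols carried by more than 1 row were read from the row with the most reads.

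Alternatives fixed beforehand were total-count, DESeq2 1.42.0 size factor and upper-quartile scaling, library sizes without mtDNA genes, TPM with a pseudocount of 1 or 0.1, a prior of 5 reads, no filter or a minimum mean of 5 CPM, thresholds of 1.5-fold and 3-fold, means for medians, and 20 expression bins. TPM centred on the median gene (pseudocount of 1), the mtDNA share of summed TPM and the counts without Derpc were added after the data were examined. An annotation of another release (GENCODE, mouse) was used only to see that the loci of Derpc and Chtf8 overlap.

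The calculation was tested on simulated data, with counts drawn for 22063 genes from the means and sizes of these libraries and 200 genes changed by known amounts. The 95% intervals held the true ratio for 95.6% of genes. Of genes changed by 1.5 on the log2 scale, 99.0% were found at least 2-fold apart, and all of those changed by 2. Of 11938 unchanged genes, 27 were found at least 2-fold apart. The draws held counting error only, with no difference between hearts or library preparations. Of 200 random lists of 20 genes, 3.5% fell outside the central 95%.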

Results

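Messenger RNA from mouse heart was sequenced in 2 libraries, 1 per group. The GFP library was the control, and the COX8-AGO2 library came from treatment with a recombinant adeno-associated virus (rAAV, a gene delivery vector) named for COX8 and Ago2. Whether the GFP tissue received a vector too is not stated here. Ago2 is the Argonaute protein that carries microRNAs to their targets. COX8 is a subunit of cytochrome c oxidase whose targeting sequence is widely used to send proteins into mitochondria; the construct itself is not described in the labels. The estimated read counts of all genes summed to 14615982 in the GFP library and 15065345 in the COX8-AGO2 library, with reads on 14864 and 14981 genes. With 1 library per group, no difference below has a replicate check and no p-value is given. Ranges after a ratio are exact 95% counting intervals, which cover counting error only and compare these 2 libraries, not the conditions. The labels do not say how many animals went into a library or whether the animals were diabetic.

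The comparison of COX8-AGO2 with GFP asks how the heart transcriptome differs after Ago2 delivery, in a series whose title ties Ago2 to translation of mitochondrial genes in diabetic cardiomyopathy. PolyA RNA-seq reads the level of mRNAs and not their translation. Genes of the integrated stress response, the programme driven by the transcription factor ATF4, were higher in the COX8-AGO2 library, led by the mitochondrial folate enzyme gene Mthfd2 at 26.0-fold (17.1 to 44.0). Interferon-stimulated genes were higher by a median of 1.81-fold, with 34 of 35 measured members higher. Of the 13 mRNAs encoded by mitochondrial DNA (mtDNA), 12 were higher and mt-Co1 was lower. Fatty acid oxidation genes were lower by a small median log2 ratio of −0.25. Targets of PPAR-alpha, the nuclear receptor for fatty acids, were lower too, led by Pdk4, the kinase that restrains pyruvate oxidation, at 3.16-fold lower (3.08 to 3.24).

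Ago2 (ENSMUSG00000036698), the delivered gene, had 1172 reads in the GFP library and 2489 in the COX8-AGO2 library, or 78.6 and 169 CPM (counts scaled to a common library size). Its ratio was 2.15-fold (2.0 to 2.30), a log2 ratio of 1.10 (1.00 to 1.20). The labels do not say whether the delivered sequence is the mouse gene, so its reads may or may not be counted here, and gene totals cannot separate them from reads of the endogenous gene. Ago4 was 1.15-fold lower (0.957 to 1.38), an interval that includes no difference.

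The mtDNA-encoded mRNAs took 36.7% of reads in the GFP library (exact interval 36.6 to 36.7) and 41.3% in the COX8-AGO2 library (41.3 to 41.3), a difference of 4.62 percentage points. The median log2 ratio of the 13 mRNAs was 0.51, at percentile 100 of 10000 random gene lists of the same size drawn from the most abundant expression bin. That match is loose, since 9 of the 13 exceeded every nuclear gene in mean CPM; 10 of the 13 had a higher log2 ratio than any of the 230 nuclear genes in the bin. The 12 mRNAs other than mt-Co1 had log2 ratios from 0.26 for mt-Nd6 to 1.02 for mt-Nd4l, with a median of 0.53. The most abundant of them by reads in the GFP library were mt-Co3, 1.42-fold higher (1.41 to 1.42), mt-Cytb, 1.53-fold higher (1.52 to 1.53), and mt-Nd4, 1.29-fold higher (1.28 to 1.29). In the opposite direction, mt-Co1, which encodes the catalytic subunit of cytochrome c oxidase, went from 13.5% to 9.37% of reads, a log2 ratio of −0.47. Part of the spread among the 12 followed transcript length. The effective lengths implied by the deposited counts and TPM (transcript abundance scaled by length) were shorter for short genes in the GFP library relative to long genes, by 0.48 on the log2 scale for mt-Nd4l and 0.43 for mt-Atp8. With TPM centred on the median gene, a scale chosen after the data were examined, the median of the 12 was 0.43, mt-Nd4l was 0.51, mt-Nd6 was 0.08 (−0.13 without centring) and mt-Co1 was −0.52. Without centring all of these TPM values were lower, since that scale moved the median of all genes by −0.21. In the pairs mt-Atp8 and mt-Atp6, and mt-Nd4l and mt-Nd4, the coding regions overlap on 1 transcript per pair, and mt-Nd6 lies antisense to other mtDNA transcripts. Strand use in counting is not given in the sources used here, so values within these sets are uncertain.

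**Figure D1:**
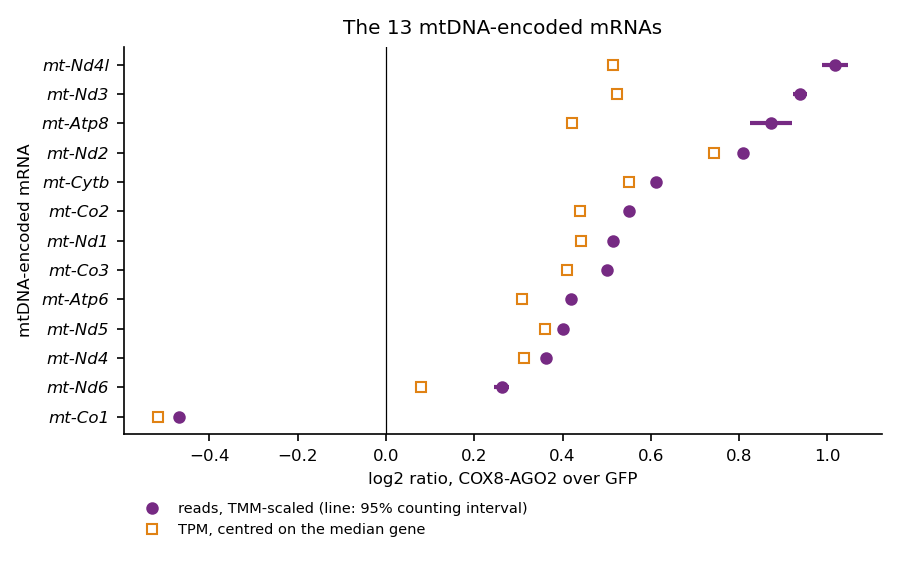
Log2 ratio of COX8-AGO2 over GFP (x axis) for each of the 13 mtDNA-encoded mRNAs (y axis), 1 library per group. Filled circles are TMM-scaled reads with the 95% counting interval as a line, and open squares are TPM centred on the median gene; mt-Co1 lies at −0.47 and −0.52, and the other 12 lie above 0 on both scales, of which mt-Nd6 is at −0.13 if TPM is not centred.

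Nuclear-encoded subunits of the same respiratory complexes stayed within 1.5-fold in all 77 cases. Their median log2 ratio was 0.043 (percentile 99.99), and it turned to −0.016 with total-count scaling and to −0.076 with centred TPM (percentile 20.5), so no direction is given. The 37 complex I subunits had a median of 0.043 and the 40 subunits of complexes II to V had 0.053, and both were negative on those same scales. Of the 77, 49 were higher and 28 lower. Ndufb1 was 1.37-fold higher (1.20 to 1.56), Cox8a 1.34-fold higher (1.23 to 1.46) and Ndufs1 1.17-fold lower (1.13 to 1.21). The vector is named for COX8, and whether its reads count under Cox8a cannot be told. Medians near 0 were also seen for 78 mitochondrial ribosomal proteins (0.026, percentile 89.7), 39 mitochondrial gene expression factors (0.066, percentile 94.7), 31 import components (0.064, percentile 97.0) and 24 genes of mitochondrial biogenesis and dynamics (−0.045, percentile 27.5). Among these, Fastkd1, a mitochondrial RNA-binding factor, was 1.54-fold higher (1.29 to 1.86), and Timm17b, part of the inner membrane translocase, was 1.5-fold lower (1.20 to 1.88). The 13 measured genes of the microRNA machinery had a median of −0.043 (percentile 29.5), with Mov10, an RNA helicase, 1.75-fold higher (1.26 to 2.48).

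Across 12138 genes with a mean of at least 1 CPM, 92.3% differed by less than 1.5-fold between the libraries. At least 2-fold differences were found for 177 genes higher and 84 lower in the COX8-AGO2 library. Counting error alone placed 27 of 11938 unchanged genes that far apart in simulated libraries of this depth. The simulation held no difference between hearts or library preparations, so 27 is not the number that 2 hearts of the same group would give. TPM, a fixed total of which the mtDNA mRNAs took 66.4% and 72.5%, moved the median of all genes by −0.21 and gave 33 higher and 63 lower with a pseudocount of 1, and 64 and 150 with 0.1. Centred on that median, with a pseudocount of 1, it gave 52 and 33; this pseudocount draws the ratios of low genes toward 0. Most of these genes were low: among 9651 genes with a mean of at least 5 CPM, 43 were higher and 13 lower.

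**Figure D2:**
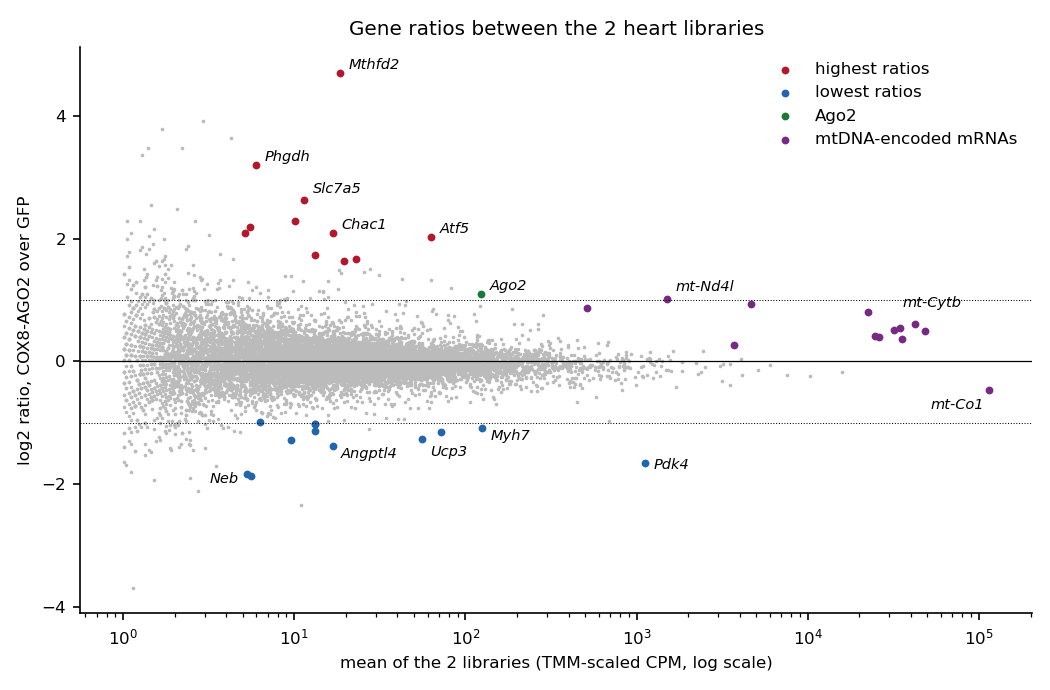
Log2 ratio of COX8-AGO2 over GFP (y axis) against the mean of the 2 libraries in TMM-scaled CPM (x axis, log scale), 1 point per measured gene with reads in both libraries. Coloured points are Ago2, the mtDNA-encoded mRNAs and the genes with the highest and lowest ratios at a mean of at least 5 CPM, and dotted lines mark 2-fold; Mthfd2 lies at 4.70 and Pdk4 at −1.66.

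Of the 12 genes with the highest ratios at a mean of at least 5 CPM, 8 belonged to the fixed list of the mitochondrial and integrated stress response. Mthfd2 went from 20 to 527 reads. Genes of serine synthesis followed, with Phgdh at 9.21-fold (5.72 to 16.6) and Psat1 at 4.57-fold (3.08 to 7.19). Asns, which makes asparagine, was 4.86-fold higher (3.61 to 6.76), and Aldh18a1, which makes a proline precursor, 3.10-fold higher (2.56 to 3.78). Chac1, which degrades glutathione, was 4.25-fold higher (3.41 to 5.38), the transcription factor gene Atf5 4.08-fold (3.65 to 4.59) and the pseudokinase gene Trib3 3.31-fold (2.62 to 4.25). The amino acid transporter genes Slc7a5 and Slc1a4, outside that list, were 6.20-fold (4.59 to 8.71) and 4.27-fold (2.87 to 6.72) higher. Over the 24 measured genes of the list the median log2 ratio was 0.98 (percentile 100), with 13 at least 1.5-fold higher and none at least 1.5-fold lower. The secreted stress factor Gdf15, with 9 and 117 reads, was 12.5-fold higher (6.69 to 29.5), and the proline enzyme gene Pycr1, with 5 and 60 reads, 11.1-fold higher (4.92 to 38.7). Members without such differences, chosen for mention after their values were seen, were the mitochondrial chaperone gene Hspd1 at a log2 ratio of 0.05, the mitochondrial protease subunit gene Clpp at −0.12 and Cebpb at −0.48. Atf4 itself, also chosen after its value was seen, was at 1.20.

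The remaining pair among the highest ratios needs care. Derpc had 0 and 185 reads, at least 62.3-fold higher against a floor of 3 reads, but its annotated locus overlaps Chtf8, which went from 803 to 618 reads, and the genes together had 803 reads in each library. Tgtp1, an interferon-induced GTPase gene at 3.19-fold higher (2.67 to 3.83), has the near-identical copy Tgtp2, with which reads can be shared.

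Interferon-stimulated genes formed a broad group, with a median log2 ratio of 0.86 (percentile 100) and 26 of 35 measured members at least 1.5-fold higher. Irf7, a transcription factor gene of the interferon response, was 2.81-fold higher (2.32 to 3.44), Gbp3 2.75-fold (2.34 to 3.26), Ifit3 2.71-fold (2.24 to 3.29) and Gbp4 2.64-fold (2.29 to 3.07). Antigen presentation genes had a median of 0.30 (percentile 100), with the peptide transporter gene Tap1 2.02-fold higher (1.65 to 2.48) and the class I gene H2-K1 1.81-fold higher (1.71 to 1.91). Leaving out the 3 genes shared with the interferon list, the median of the other 12 was 0.24. Families such as the Gbp, Ifit and H2 genes have close paralogs, so their single values are uncertain where counting could split reads. Of the 13 measured macrophage and monocyte markers 12 were higher, 3 of them at least 1.5-fold, with a median of 0.38 (percentile 100) and Cd68 at 1.93-fold (1.48 to 2.56). Only 13 of the 27 listed inflammatory cytokine and chemokine genes were measured. Their median, −0.036 (percentile 26.1, counting interval −0.14 to 0.17), did not stand apart. With centred TPM it was 0.097 over 15 genes (percentile 88.8), also inside the random range, so no direction is given. Cxcl9 was 2.02-fold higher (1.55 to 2.65) while Lcn2 was 1.84-fold lower (1.11 to 3.18).

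**Figure D3:**
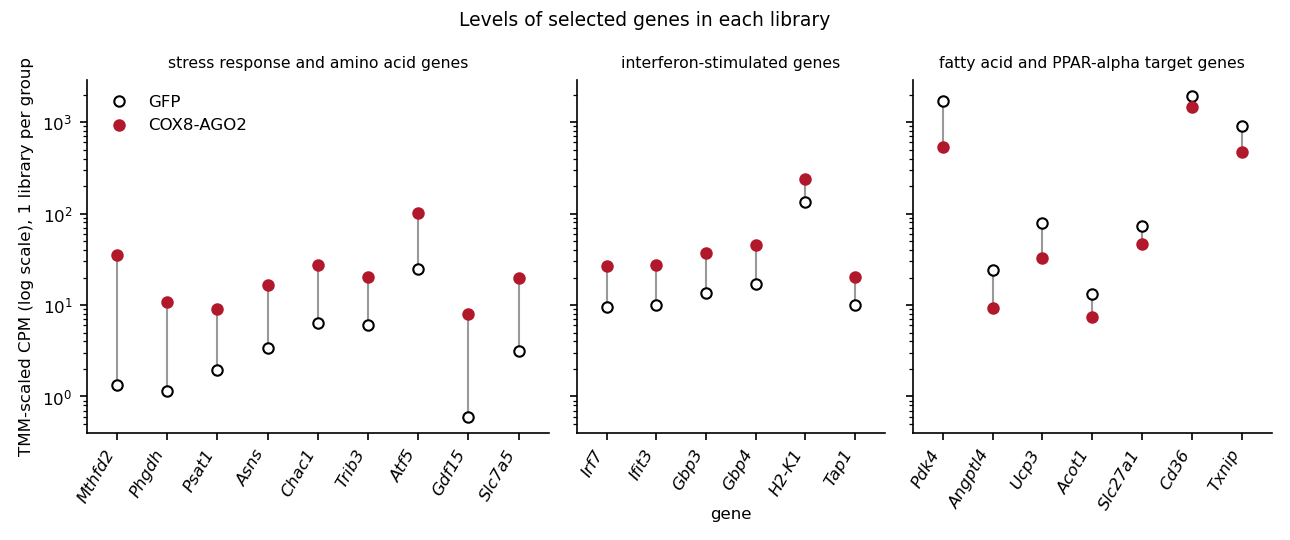
TMM-scaled CPM (y axis, log scale) of selected genes in the GFP library (open circles) and the COX8-AGO2 library (filled circles), 1 library per group, in 3 panels. The genes were picked from named genes with large ratios, so their shared direction within a panel is no separate result, and members without such a difference, such as Cebpb, are not shown. Those of stress response and amino acid supply, and the interferon-stimulated genes with H2-K1 of the antigen presentation list, are higher in the COX8-AGO2 library. The fatty acid and PPAR-alpha target genes and Txnip are lower, with Pdk4 at 1707 and 541 CPM.

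Fatty acid oxidation genes were lower as a group. The median log2 ratio was −0.25 over 24 genes (percentile 0), of which 23 were lower, mostly by less than 1.5-fold. The fatty acid transporter gene Slc27a1 was 1.57-fold lower (1.43 to 1.73), Decr1 1.36-fold (1.3 to 1.42) and the uptake receptor gene Cd36 1.33-fold (1.31 to 1.36). Targets of PPAR-alpha had a median of −0.32 over 19 genes (percentile 0), and 5 were at least 1.5-fold lower. These included Pdk4, with 25468 and 7983 reads, Angptl4, an inhibitor of lipoprotein lipase, at 2.59-fold lower (2.13 to 3.18), the mitochondrial carrier gene Ucp3 at 2.41-fold lower (2.16 to 2.68) and Acot1 at 1.78-fold lower (1.40 to 2.28). Insulin and glucocorticoid response genes had a median of −0.45 over 21 genes (percentile 0), with 7 at least 1.5-fold lower, among them Irs2 at 1.83-fold (1.51 to 2.22). Without Pdk4 and Angptl4, which the PPAR-alpha list also holds, that median was −0.44. Only 5 of the 14 adipocyte markers were measured, 4 lower and 1 higher, with a median of −0.28 (percentile 1.24). Lipe was 1.42-fold lower (1.29 to 1.56) and Scd1 1.23-fold higher (1.08 to 1.41), and Fabp4 is also on the endothelial list. These few genes do not show a difference in adipocyte content. Ketone body and branched-chain amino acid genes had a median of −0.14 (percentile 0.85) over 18 genes, against which Bdh1, of ketone body use, was 1.71-fold higher (1.57 to 1.88). Glycolysis genes had a median of 0.083 (percentile 99.92), which was 0.031 with centred TPM and negative with uncentred TPM, and Pgam1 was 1.46-fold higher (1.34 to 1.60). TCA cycle genes had a median of −0.083 (percentile 25.7). The antioxidant list had a median of 0.0019 (percentile 72.3), while its member Txnip, which inhibits thioredoxin and is induced by glucose, was 1.95-fold lower (1.90 to 2.01).

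The 13 measured cardiac stress and fetal genes had a median of −0.021 (percentile 59.0), with Nppb, the natriuretic peptide gene, 2.5-fold higher (2.26 to 2.77), Nmrk2 3.35-fold higher (2.15 to 5.54) and the beta myosin heavy chain gene Myh7 2.12-fold lower (1.98 to 2.27). Nppa was at 1.01-fold (0.926 to 1.10). Sarcomere and calcium handling genes had a median of −0.066 (percentile 42.2), with Trdn 1.52-fold lower (1.43 to 1.63). Ion channel and conduction genes had a median of −0.15 over 20 genes (percentile 0.14), of which 17 were lower; with centred TPM the median was −0.097, inside the random range (percentile 3.67). Among them were the inward rectifier channel gene Kcnj2 at 1.91-fold lower (1.70 to 2.16) and the gap junction gene Gja1 at 1.52-fold higher (1.45 to 1.60). Other genes with the lowest ratios at a mean of at least 5 CPM were Scd4 at 3.57-fold lower (2.45 to 5.44), Rasgef1b at 2.43-fold (1.88 to 3.19), the cytokine signalling inhibitor gene Cish at 2.23-fold (2.03 to 2.45), Phlda1 at 2.19-fold (1.77 to 2.74), Mybpc2 at 2.04-fold (1.65 to 2.54), Etfbkmt at 2.03-fold (1.64 to 2.53) and Bmf at 1.99-fold (1.46 to 2.75). Neb was 3.66-fold lower in reads (2.53 to 5.54). Its deposited TPM values, 0.43 and 0.22, differed by less even without a pseudocount, and the cause of that gap was not tested. At these values the pseudocount of 1 leaves centred TPM (−0.02) uninformative.

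Extracellular matrix genes had a median of 0.19 over 32 genes (percentile 100), with Col3a1 1.44-fold higher (1.37 to 1.5) and Ccn2 1.51-fold lower (1.39 to 1.64). The median was 0.16 with centred TPM and −0.049 with uncentred TPM and a pseudocount of 1. Leaving out Col1a1, Col1a2, Col3a1 and Lum, which are also fibroblast markers, the median of the other 28 was 0.18 (percentile 100). Cell cycle genes had a median of 0.65 over 21 genes (percentile 100), with 12 at least 1.5-fold higher; Top2a was 2.23-fold higher (1.66 to 3.05), and Cdk1, at 11 and 35 reads, 3.12-fold higher (1.60 to 7.02). With centred TPM the median of the list was 0.31 over 13 measured genes (percentile 99.94), still above the random range. The 108 measured genes of the Cell cycle pathway in the deposited annotation had a median of 0.029 (percentile 85.0), inside the random range. Of these, 15 were at least 1.5-fold higher and 2 at least 1.5-fold lower. Cytosolic ribosomal protein genes had a median of 0.14 over 50 genes (percentile 100), and 0.039 with centred TPM, where the short genes Rps28 and Rpl38 turned negative. The cell death list held members in both directions, with 12 higher and 10 lower, a median of 0.14 (percentile 98.0, counting interval −0.084 to 0.21), Trp53 1.72-fold higher (1.41 to 2.11) and Bcl2l1 1.70-fold lower (1.53 to 1.89). Heat shock and endoplasmic reticulum chaperones had a median of 0.064 (percentile 98.5). With centred TPM both lists lay inside the random range, cell death at 0.11 (percentile 95.3) and chaperones at 0.025 (percentile 93.4). No separation from random lists was seen for immediate early genes (−0.070, percentile 10.2; Myc 2.49-fold higher, 1.70 to 3.79), clock genes (−0.051, percentile 17.9) or autophagy and lysosome genes (−0.016, percentile 65.3; Fbxo32 1.62-fold lower, 1.52 to 1.72). In all, 17 of the 30 gene lists lay outside the central 95% of their random lists, 12 above and 5 below, where independent draws of genes would give 1.5. With centred TPM 12 of the 30 did, without both complex subunit lists, ion channels, cell death and chaperones. Genes of a list can vary together between any 2 hearts, and some lists share genes. The 1.5 is therefore not the number that a difference between 2 hearts or libraries alone would give.

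**Figure D4:**
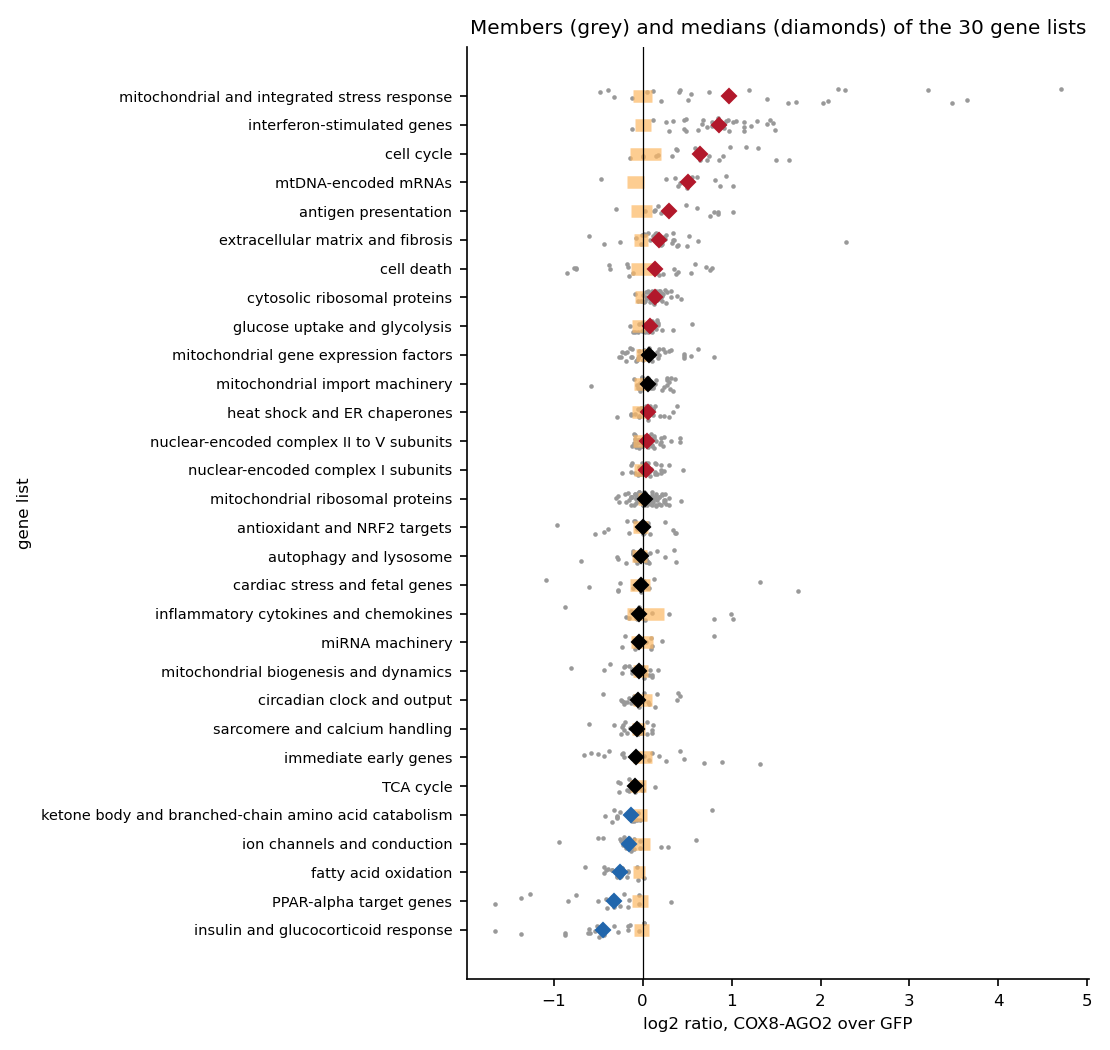
Log2 ratio of COX8-AGO2 over GFP (x axis) for the 30 gene lists (y axis), 1 library per group. Grey points are measured members, diamonds are medians, and bars span the central 95% of 10000 random lists matched on expression bins (loosely for the mtDNA mRNAs); red medians lie above the bar and blue ones below it. The medians of the 2 lists of nuclear-encoded complex subunits turn negative with total-count scaling and with centred TPM.

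Marker medians of most heart cell types lay inside their random range, with members in both directions. Medians were −0.051 for ventricular cardiomyocytes (percentile 61.6), 0.0039 for atrial cardiomyocytes (50.8), −0.0064 for endothelial cells (64.3), −0.11 for endocardial and lymphatic endothelium (7.43), 0.024 for smooth muscle cells and pericytes (80.1) and −0.25 for Schwann cells and neurons (6.52), where 5 of 6 measured genes were lower. Among smooth muscle and pericyte markers, Cnn1 was 1.93-fold lower (1.25 to 3.08), Myh11 1.49-fold lower (1.37 to 1.62) and Tagln 1.40-fold lower (1.24 to 1.59), while Vtn was 1.65-fold higher (1.43 to 1.92). The lymphatic genes Ccl21a and Mmrn1 were 1.62-fold (1.43 to 1.83) and 1.49-fold (1.29 to 1.74) lower, and the Schwann cell genes Sox10 and Plp1 1.89-fold (1.04 to 3.68) and 1.57-fold (1.08 to 2.32) lower. Fibroblast markers had a median of 0.099 (percentile 98.6; 0.075 with centred TPM, at the edge of the random range), with Col1a1 1.41-fold higher (1.31 to 1.52); without the 4 genes shared with the matrix list, the median of the other 8 was 0.0040 (percentile 70.4). Erythroid markers had a median of 0.30 (percentile 99.86), with Hba-a2, a member of a near-identical pair, 1.3-fold higher (1.25 to 1.35). Only 5 of the 10 epicardial and mesothelial markers were measured, with a median of 0.98 (percentile 99.99, counting interval 0.32 to 2.15). With centred TPM only 2 were measured, with a median of 0.21 and no percentile. Upk3b, at 5 and 82 reads, was 15.2-fold higher (6.82 to 52.4), and Msln, at 3 and 35 reads, 10.3-fold higher (3.72 to 59.9). Upk3b, Msln and Krt18, at 0.34, 0.20 and 0.74 CPM in the GFP library, passed the filter only through the COX8-AGO2 library. The filter thus favoured members high in that library, and Krt8, which was not higher, fell below it. Under 5 genes were measured for B cells and plasma cells (2 genes, median 0.52), neutrophils (3 genes, −0.047), skeletal muscle (3 genes, 0.031) and sex-linked genes (4 Y-linked genes, −0.35), so no percentile is given for them, and none of the T and NK cell markers reached a mean of 1 CPM.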

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

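The alternatives with TPM centred on the median gene, without Derpc and with the share of summed TPM were chosen after the data were examined. No paired analysis was possible because there was 1 library per group; leaving out a library was not possible either. Removing mitochondrial ribosomal and transfer RNAs from the mtDNA share was not run, since the table held only the 13 mRNAs. Where a value below moved, the cause was not tested unless the setting itself fixes it, as a filter or a threshold does. The number of genes at least 2-fold higher, 177, became 319 with library sizes without mtDNA genes, 33 and 64 with TPM and a pseudocount of 1 and 0.1, 52 with centred TPM, 1224 with no filter, 43 at a mean of at least 5 CPM, 595 at 1.5-fold and 49 at 3-fold. The number of genes at least 2-fold lower, 84, became 150 with TPM and a pseudocount of 0.1, 33 with centred TPM, 52 with a prior of 5 reads, 990 with no filter, 13 at a mean of at least 5 CPM, 342 at 1.5-fold and 15 at 3-fold. The Ago2 log2 ratio, 1.10, was 0.75 and 0.85 with TPM and the 2 pseudocounts and 0.97 with centred TPM. The median of the mtDNA-encoded mRNAs, 0.51, was 0.45 with total counts, 0.50 with DESeq2 size factors, 0.52 with upper-quartile scaling, 0.56 with library sizes without mtDNA genes, 0.21 with TPM and either pseudocount, 0.42 with centred TPM and 0.52 as a mean. The share of counts from mtDNA genes differed by 6.09 percentage points of summed TPM. For nuclear-encoded OXPHOS subunits the median, 0.043, was 0.093 with library sizes without mtDNA genes, −0.016 with total counts, −0.29 with TPM and either pseudocount, and −0.076 with centred TPM. Complex I subunits were at −0.017 with total counts, −0.28 with TPM and either pseudocount, and −0.070 with centred TPM, and the median of nuclear-encoded complex II to V subunits was at −0.0061, −0.30 and −0.30, and −0.082. Uncentred TPM, which lowers the median of all genes by −0.21, also reversed glycolysis (−0.18 with either pseudocount), extracellular matrix (−0.049 and −0.050), cell death (−0.11 and −0.12), heat shock and ER chaperones (−0.19 with either), cytosolic ribosomal proteins (−0.17 and −0.18), fibroblast markers (−0.14 and −0.15) and, with a pseudocount of 1, epicardial and mesothelial markers (−0.0033). Of the 11 marker lists with a percentile, 5 lay outside the random range, and 3 did at a mean of at least 5 CPM and for members of at least 5 CPM. With centred TPM 9 had a percentile and 3 lay outside in this draw of random lists, but 4 in another, since fibroblast markers sat on the edge, at percentile 97.65 in that one. The number of gene lists outside the random range, 17, lay between 12 and 19 under every setting run. Over 2386 values of named genes and lists under these settings, 2280 kept their sign and 106 did not, 40 of them with a main log2 value of at least 0.1 either way. Of 42 named genes at least 2-fold apart, all 42 remained so with DESeq2 size factors and 39 with total counts, and with centred TPM 25 of the 35 measured there did. Depth limits genes near 1 CPM, where few reads leave wide counting intervals.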

Other observations

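Of the tests in this part, only that of the cytosolic aminoacyl-tRNA synthetases was written down before its result was seen; all the others, and the 7 added gene lists, were chosen after the data were examined. Cytosolic aminoacyl-tRNA synthetase genes had a median log2 ratio of 0.42 in the COX8-AGO2 library, with 18 of 20 higher and 8 at least 1.5-fold higher, led by Mars1 at 0.94, Cars at 0.87 and Sars at 0.85. Their 17 mitochondrial counterparts had a median of 0.045 (percentile 75.1). Serine, glycine and one-carbon enzyme genes had a median of 0.41 over 14 genes (percentile 99.97), but 6 of these belong to the stress response list, and the other 8 had a median of 0.28 (percentile 97.2), inside the random range. Of those 8, Aldh1l2, the mitochondrial formyltetrahydrofolate dehydrogenase gene, was at 1.31. Amino acid transporter genes had a median of 0.27 over 16 genes (percentile 99.99), a list drawn up after Slc7a5 and Slc1a4 were seen among the highest ratios; without those genes the median of the other 14 was 0.16 (percentile 98.0), with Slc6a9, a glycine transporter gene, at 1.66. Mitochondrial chaperones and proteases had a median of 0.15 over 10 genes (percentile 99.7), from Hspe1 at 0.54 to Clpx at −0.32, while chaperones of the endoplasmic reticulum alone had a median of 0.041 (percentile 84.7).

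Over 325 pathways of the annotation in the deposited table, 84 lay outside the central 95% of random lists, 64 above and 20 below, where chance gives 16.3; pathways share genes and are not independent. Among the highest medians were Allograft rejection at 0.36 and One carbon pool by folate at 0.25, and among the lowest Steroid hormone biosynthesis at −0.28 and Fatty acid degradation at −0.23. Circadian rhythm lay at −0.13 over 29 genes (percentile 0.20), unlike the fixed clock list. Fgf21, a hormone gene of the mitochondrial stress response, had 0 reads in the GFP library and 21 in the COX8-AGO2 library, at least 7.08-fold higher against the floor of 3 reads. Lrrn4, a mesothelial marker, had 0 and 17 reads, at least 5.73-fold higher, while the mesothelial marker Krt8 had 13 and 11 reads and Wt1 was at 0.25. None of 9 lung epithelium genes reached a mean of 1 CPM. Ptprc, a gene of white blood cells in general, had 143 and 142 reads.

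The divergence of mt-Co1 from the 12 other mtDNA mRNAs is the first pattern weighed. A shorter fragment length in the COX8-AGO2 library, which favours short genes, would vanish under centred TPM, where the 12 had a median of 0.43 and mt-Co1 lay at −0.52. The share of reads freed by mt-Co1 would raise every other gene by 0.068 on the log2 scale, and the 12 exceeded that by 0.41 under total-count scaling. A difference between the tissues or libraries unrelated to the delivered gene cannot be told apart from an effect of Ago2, because there was 1 library per group. Both stay open, and reads shared with nuclear copies of mtDNA were not tested.

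Interferon-stimulated genes are the second pattern. More macrophages and monocytes in the tissue piece would lift these genes by no more than the macrophage markers, but their median exceeded that of the markers by 0.47 (bootstrap 95% interval over genes 0.29 to 0.64). That interval treats the genes of a list as independent and covers no difference between hearts. With centred TPM their median was 0.72, but that test could hardly have come out otherwise. Among genes above 5 TPM, the implied effective length of the shortest decile shifted by a median of only 0.077 on the log2 scale relative to the longest. It is the small size of that shift that argues against fragment length. A response to the vector, to the delivered gene or to another exposure of the animals, and interferon signalling within a larger macrophage population, remain open and were not tested. The GFP tissue may have received a vector as well.

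The integrated stress response is the third pattern. With centred TPM its median was 0.97, and here too the shift of effective length was too small for that test to come out otherwise. The small shift itself argues against fragment length. Chaperones of the endoplasmic reticulum were not higher by a similar amount, since the stress list exceeded them by 0.93 (bootstrap 95% interval over genes 0.30 to 1.95). That interval, too, covers no difference between hearts. The difference argues only against a response of that compartment that lifts both lists alike. One that lifts the stress genes without the chaperones was not tested and remains open. The cytosolic synthetases lay at percentile 100 of random lists, so the higher genes extended to them. That list was added after the data were examined. Its result widens the pattern and does not separate an amino acid cause from another trigger. The trigger of the stress response, whether the delivered protein, mitochondrial load or amino acid status of the animals, was not tested.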
